A study of Caenorhabditis elegans with 8 samples.

How the data were processed

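Gene expression was measured by RNA sequencing in 8 samples of whole adult Caenorhabditis elegans, 4 fed control bacteria and 4 fed bacteria producing double-stranded RNA against mtch-1. Per the labels' protocols, the worms were kept at 20 °C on plates with 1 mM IPTG. The HT115 Escherichia coli carried either the empty L4440 vector (EV) or the mtch-1 sequence and were induced with 5 mM IPTG for 3 h at 37 °C. Feeding ran from hatching to day 3 of adulthood, when about 200 adults were frozen. Total RNA was taken up in Trizol and column-purified, and libraries were made with an Illumina procedure whose RNA selection and strandedness are not given in the sources used here.

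One table covering all samples was used. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 were used with the WBcel235 build, with no version given for DESeq2 and no settings given. Per the file headers, the authors deposited read counts per gene, which are whole numbers. The authors also deposited a normalized signal, which equals the count divided by 1 size factor per sample, together with its mean per group. The authors' FPKM values divide each count by the gene length and by 1 library size per sample. That library size lay 4.43% to 5.38% above the TMM effective library size computed here from the counts. The authors' log2 fold changes, p-values and adjusted p-values for mtch-1(RNAi) over EV complete the deposited table. The gene lengths are in bases, another unit the authors deposited. All tests here used the counts. The size-factor signal and FPKM values served only to check the units.

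The table held 20871 genes under sequence names and gave no symbols. Of these, 20589 were matched to the Ensembl annotation of the same build and 4 to RefSeq, and 278 kept their sequence name. Protein-coding genes of the mitochondrial genome were named by overlap with RefSeq. Coordinates are 1-based gene spans of that annotation on WBcel235, because in 359 genes (1.72%) the file's own span was shorter than its gene length. No counted feature lacked a gene identifier, and 0 columns of per-sample values were left without a sample.

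Groups and replicate numbers came from the sample titles. The labels do not say that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of samples within a group was closer than sampling noise: the chi-square per degree of freedom over genes was 6.78 to 15.5. Same-numbered samples of the 2 groups deviated together from their group means over the tested genes, with correlations of 0.342, 0.205, 0.242 and 0.185 for replicates 1 to 4. Each of the 8 samples correlated best with its own number in the other group. By a limit of 0.1 for all 4 pairs, set before the data were examined, the numbers pair the samples. The labels state no shared day or plate. The main test leaves the block out, as fixed beforehand.

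Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling, after the default expression filter with the 2 groups. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a call is an adjusted p under 0.05. Every adjusted p given for a gene comes from edgeR unless another tool is named. Levels are CPM values on TMM effective library sizes, as mean ± SD over 4 samples. The standard error of a log2 fold change is the fold change divided by the square root of its F value. Changes of at least 2-fold are counted by the fitted log2 fold change.

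Before the data were examined, 40 gene lists were fixed for mitochondrial, metabolic, stress, germline and tissue functions. They were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over the 40 lists. The same test with a correlation estimated per list, and fry, were run beside it. Counts of changed members are given adjusted over all genes tested and adjusted over the list alone.

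The genes named were also fixed by rule. They are mtch-1 and the 10 protein-coding genes with the largest rise and the 10 with the largest fall that passed the test, had a mean of at least 5 CPM over the 8 samples, carried a gene name and showed no overlap between groups. For each list, up to 3 changed members with the lowest adjusted p follow, or the 2 most abundant members of a list with none changed. Other list members, such as those that moved against their list (hsp-60, spg-7, cyc-2.1, icl-1, aip-1, him-3, htp-1, hsf-1, sip-1, pek-1, nhr-49, cyp-34A8, col-149 and rpl-5) and vit-5, were chosen after their values were seen.

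The scripts were tested on simulated data before use. Counts were drawn for the comparison of 4 EV with 4 mtch-1(RNAi) samples from the real means, library sizes and dispersions, with 200 genes changed, and 13070 genes passed the filter. edgeR recovered 58.2% of genes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and all of those changed by 2. False calls made up 6.59% of its calls, against 19.8% for DESeq2 and 8.24% for limma-voom. In a separate simulation, with each gene drawn independently, camera called a list of 30 genes lowered by 0.3 on the log2 scale. It did not call an unchanged list of 30 genes. Correlated lists were not simulated, so this does not measure false list calls in these data.

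Alternatives set beforehand were DESeq2-type and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no count filter, a filter of at least 50 counts in 4 samples, the replicate number as a block, removal of the 50 most abundant genes, and leaving out each sample in turn. An added alternative left out replicate 1 of both groups. It was chosen after seeing the data, because hsp-16.2, hsp-16.41 and hsp-70 were highest in mtch-1(RNAi) replicate 1. Another, also chosen after seeing the data, removed a loess trend of the signed z-score with gene length and mean level before the list tests. Total counts per sample were 18710833 to 23608608. In a single sample, a count of 0 allows up to 3 counts, or 0.126 to 0.165 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.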

Results

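The study asked how lowering mtch-1 changes gene expression in adult worms. The gene encodes a mitochondrial carrier homolog, a protein of the outer mitochondrial membrane. RNA from 4 samples of day 3 adults fed empty-vector bacteria (EV) was compared with RNA from 4 samples fed mtch-1 double-stranded RNA, written mtch-1(RNAi). Total gene counts were 20733659, 18710833, 18736440 and 23608608 for EV replicates 1 to 4, and 22748868, 22275401, 20908561 and 20626184 for mtch-1(RNAi) replicates 1 to 4. The mean total in mtch-1(RNAi) was 1.06 times that in EV (n = 4 per group; exact permutation p = 0.371, 2-sided). The number of genes with at least 1 count was 17456 ± 169.7 in EV and 18016 ± 154 in mtch-1(RNAi) (SD, n = 4), with no overlap between groups (exact 2-sided permutation p = 0.0286, or 0.0571 adjusted over 8 such sample measures). The 10 most abundant genes took 8.46% to 10.4% of a sample's counts. A comparison of 4 with 4 samples cannot give an exact 2-sided permutation p below 0.0286.

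The targeted gene was lower in every mtch-1(RNAi) sample. mtch-1 (F43E2.7, chromosome II, 7372615 to 7374166, minus strand) fell from 279 ± 11.9 CPM in EV to 47.2 ± 9.92 CPM in mtch-1(RNAi) (SD, n = 4). The log2 fold change was -2.56 (SE 0.12; edgeR adjusted p = 8.62e-08). Its level was 264, 287, 275 and 291 CPM in the EV samples and 50.5, 58.0, 34.3 and 46.1 CPM in the mtch-1(RNAi) samples. Reads from ingested double-stranded RNA, if any, are part of the counted level.

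Of 13252 genes tested, 1325 rose and 1728 fell after mtch-1(RNAi), and most changes were small. Of these 3053 genes, 243 rose and 64 fell by at least 2-fold, and 75.1% changed by less than 1.5-fold. The largest rises by the naming rule included a lipid enzyme gene, an iron storage gene and a glycolytic gene. asm-3, an acid sphingomyelinase gene, rose from 2.11 ± 0.743 to 20.0 ± 5.25 CPM (log2 fold change 3.24, SE 0.26, adjusted p = 9.77e-06). ftn-1, a ferritin gene, rose from 7.95 ± 5.17 to 40.7 ± 13.9 CPM (2.36, SE 0.38, adjusted p = 0.00107). aldo-1, a fructose-bisphosphate aldolase gene, rose from 29.4 ± 3.16 to 117 ± 13.1 CPM (2.00, SE 0.09, adjusted p = 8.62e-08). The neighbouring genes pud-4 and pud-3 on chromosome V rose by log2 fold changes of 2.70 (SE 0.23) and 2.65 (SE 0.21), and reads shared between such related genes leave their separate values uncertain. The remaining genes of the 10 were irg-4 (2.28, SE 0.42), the heat shock gene hsp-70 (2.16, SE 0.48), osg-1 (2.13, SE 0.17), the lipase gene lipl-1 (1.89, SE 0.20) and cutl-10 (1.76, SE 0.19).

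The largest falls included genes of fatty acid metabolism and of defence. fat-7, a stearoyl-CoA desaturase gene, fell from 8.91 ± 2.45 to 2.57 ± 0.538 CPM (log2 fold change -1.79, SE 0.22, adjusted p = 0.000183), and reads shared with the closely related gene fat-6 leave this value uncertain. lys-4, a lysozyme gene, fell from 44.8 ± 4.19 to 13.9 ± 1.88 CPM (-1.69, SE 0.10, adjusted p = 1.01e-06). acdh-1, an acyl-CoA dehydrogenase gene of short-chain substrates, fell from 596 ± 49 to 263 ± 50.1 CPM (-1.18, SE 0.11, adjusted p = 2.47e-05). Further falls were those of argk-1, an arginine kinase gene (-1.47, SE 0.22), spp-18 (-1.41, SE 0.24), dct-17 (-1.38, SE 0.26), the C-type lectin gene clec-41 (-1.35, SE 0.16), and ech-7 (-1.13, SE 0.22). dod-19 fell from 189 ± 27.1 to 82.4 ± 5.21 CPM and irg-8 from 234 ± 23.6 to 109 ± 4.86 CPM. mtch-1 and these 20 genes passed the test in the same direction under every alternative in which they were tested.

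**Figure D1:**
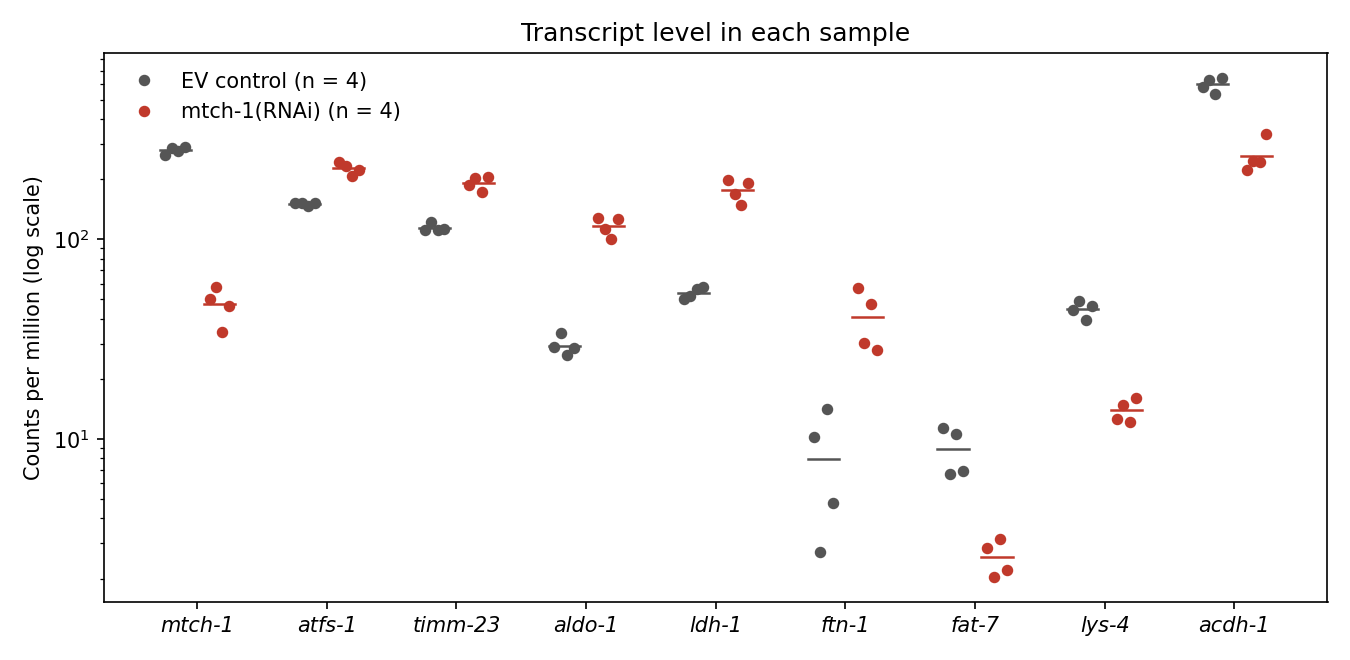
Level of 9 genes in each of the 8 samples, in CPM on a log axis. Points are samples of EV (grey) and mtch-1(RNAi) (red), n = 4 each, lines are means, and the groups do not overlap in any of the 9 genes: mtch-1 lies between 264 and 291 CPM in EV and between 34.3 and 58.0 CPM in mtch-1(RNAi). For aldo-1, ftn-1, fat-7, lys-4 and acdh-1 the naming rule itself required no overlap.

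Transcripts of the mitochondrial genome moved in opposite directions. All 11 tested mRNAs of the list of respiratory chain subunits encoded in mitochondrial DNA fell, with log2 fold changes from -0.52 (ND5) to -1.18 (ND2) and a median of -0.79. CYTB (mitochondrial DNA 4504 to 5621) fell from 1128 ± 109.0 to 580 ± 69.9 CPM, ND1 (1763 to 2635) from 456 ± 27.6 to 245 ± 33.7 CPM and COX2 (9649 to 10348) from 1076 ± 69.5 to 686 ± 46.1 CPM. All 11 also fell when adjusted over the list alone. The camera test gave adjusted p = 3.40e-11, and adjusted p = 0.270 with an estimated correlation. Both mitochondrial rRNAs rose: the small one (MTCE.7, 898 to 1593) from 38.1 ± 4.33 to 91.0 ± 6.02 CPM (1.26, SE 0.08, adjusted p = 9.92e-07), and the large one (MTCE.33, 10403 to 11354) from 28.4 ± 3.11 to 80.8 ± 15.2 CPM (1.51, SE 0.12, adjusted p = 1.21e-05). Mitochondrial rRNA made up 0.00649% ± 0.000840 of the counts in EV and 0.0176% ± 0.00199 in mtch-1(RNAi), and mitochondrial mRNA 0.732% ± 0.0591 and 0.476% ± 0.0480 (SD, n = 4). Each differed with an exact 2-sided permutation p = 0.0286, the smallest possible, or 0.0571 adjusted over 8 such sample measures, so neither passed after adjustment. The groups did not overlap in either measure. At that smallest p the adjusted value reflects the number of samples and of measures, and not the size of the change. None of 5 cytosolic rRNA genes passed the test, with log2 fold changes from -0.27 to 0.08. With the replicate block, F31C3.7 (-0.28, adjusted p = 0.00322) and F31C3.8 (-0.27, adjusted p = 0.00324) passed it as lower.

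**Figure D2:**
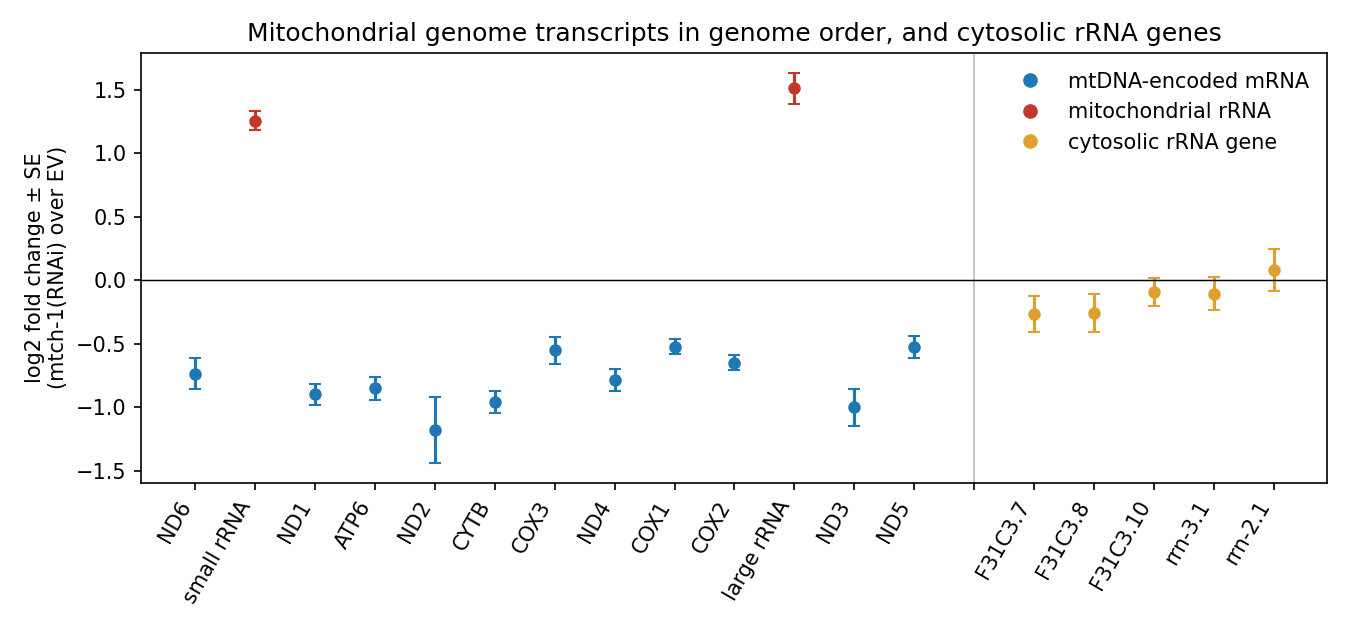
Log2 fold change of mtch-1(RNAi) over EV, with SE bars, for the 11 mRNAs and 2 rRNAs of the mitochondrial genome in genome order and for 5 cytosolic rRNA genes. The mRNAs lie between -1.18 and -0.52 and the mitochondrial rRNAs at 1.26 and 1.51.

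In the list of nuclear-encoded respiratory chain subunits, 21 of 43 genes fell and 1 rose, or 26 and 1 adjusted over the list alone. The median log2 fold change was -0.14 (camera adjusted p = 1.13e-08; adjusted p = 0.270 with an estimated correlation). asb-1 fell by 0.52, atp-1 by 0.48 and ucr-1 by 0.38 on the log2 scale, and the gene that rose was cyc-2.1, a cytochrome c gene (0.27, adjusted p = 0.00051). In the list of the mitochondrial unfolded protein response, 7 of 15 genes rose and 2 fell, and the counts were the same adjusted over the list alone. The inner membrane translocase gene timm-23 rose from 114 ± 4.91 to 192 ± 15.6 CPM (0.75, SE 0.06), the transcription factor gene atfs-1 from 150 ± 2.52 to 226 ± 15.3 CPM (0.59, SE 0.05) and the chaperone gene hsp-6 from 1017 ± 38.1 to 1351 ± 77.6 CPM (0.41, SE 0.05). The chaperonin gene hsp-60 (-0.58, adjusted p = 0.00054) and the protease gene spg-7 (-0.50, adjusted p = 0.000491) fell. The list passed camera (adjusted p = 0.0317; adjusted p = 0.289 with an estimated correlation) but not without mtch-1(RNAi) replicate 3 (adjusted p = 0.0575). Of 69 mitochondrial ribosomal protein genes, 16 rose and 6 fell, or 17 and 7 adjusted over the list alone, with mrpl-9 at 0.68 and mrps-11 at 0.48. This list did not pass camera (adjusted p = 0.130), but did without mtch-1(RNAi) replicate 1 (adjusted p = 0.0335) and with the stricter count filter (adjusted p = 0.0364). Among 22 import and dynamics genes, 4 rose and 4 fell, or 8 and 6 adjusted over the list alone; tomm-7 rose by 0.46 and vdac-1 fell by 0.31 on the log2 scale (camera adjusted p = 0.532), and 7 rose and 5 fell with the replicate block. Of 16 mitochondrial carrier genes, mfn-1 rose (0.33) and ant-1.1 (-0.28) and misc-1 (-0.22) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.959).

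Most genes of the citric acid and glyoxylate cycle list fell. Of its 22 genes, 16 fell and 1 rose, or 17 and 1 adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 6.85e-10; adjusted p = 0.270 with an estimated correlation). idha-1 fell from 188 ± 3.32 to 139 ± 3.69 CPM and sucl-2 from 220.4 ± 5.53 to 171 ± 7.50 CPM, while icl-1, which encodes the glyoxylate cycle enzyme, rose (0.74, adjusted p = 0.0221). The icl-1 call was lost without EV replicate 3 (adjusted p = 0.0595) or 4 (0.0695) and in DESeq2 (0.0632). In glycolysis, 5 of 18 genes rose and 9 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.333). Beside aldo-1, the lactate dehydrogenase gene ldh-1 rose from 54 ± 3.38 to 176 ± 22.3 CPM (1.71, SE 0.08), and gpd-1 fell from 430 ± 20.5 to 280 ± 27.4 CPM (-0.62, SE 0.07). In fatty acid synthesis and desaturation, 8 of 23 genes fell and 2 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.289 with an estimated correlation). That call was lost without mtch-1(RNAi) replicate 2 (adjusted p = 0.0572) with the stricter count filter (adjusted p = 0.0625), and once a trend of the change with gene length and expression level was removed (adjusted p = 0.310), an alternative chosen after seeing the data, although the median did not shrink (-0.16 before and -0.17 after). Beside fat-7, lpin-1 fell (-0.30), and the desaturase gene fat-3 (0.57) and the nuclear receptor gene nhr-49 (0.13) rose. The nhr-49 call was lost without EV replicate 2 (adjusted p = 0.0517) or 3 (0.0639), without mtch-1(RNAi) replicate 1 (0.0911), and with no count filter (0.0528). In the methionine and phosphocholine list, 8 of 18 genes fell and 0 rose, or 9 and 0 adjusted over the list alone (median -0.20, camera adjusted p = 0.000879; adjusted p = 0.270 with an estimated correlation). The cystathionine gamma-lyase gene cth-1 fell by 0.98 and the S-adenosylmethionine synthetase gene sams-3 by 0.49 on the log2 scale. The replicate block gave 1 gene of that list that rose and 9 that fell.

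Of 30 fatty acid oxidation and lipolysis genes, 4 rose and 8 fell, with the same counts adjusted over the list alone; the list did not pass camera (adjusted p = 0.782), and 7 rose and 10 fell with the replicate block. In the iron and heme list, 4 of 19 genes rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.478), with hrg-9 at 1.48 beside ftn-1. Of 11 hypoxia and HIF-1 target genes, nhr-57 rose (0.63) and rhy-1 (-0.34) and egl-9 (-0.23) fell, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.836), and these 3 calls were fragile. In the fit with the replicate block, 3 genes of the list rose and 2 fell. The rhy-1 call was lost without EV replicate 2 (adjusted p = 0.0749) or 4 (0.0644), or mtch-1(RNAi) replicate 1 (0.0610) or 3 (0.0514). The egl-9 call was lost without EV replicate 1 (adjusted p = 0.0803), 3 (0.0839) or 4 (0.0596), without mtch-1(RNAi) replicate 1 (0.0782) or 4 (0.103), and with no count filter (0.0608). The nhr-57 call was lost without EV replicate 2 (adjusted p = 0.0785), 3 (0.0574) or 4 (0.10), without mtch-1(RNAi) replicate 1 (0.0891), 3 (0.0744) or 4 (0.0687), and in limma-voom (0.0622).

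Proteasome genes fell as a group. Of 36 genes, 30 fell and 1 rose, or 33 and 1 adjusted over the list alone, with a median log2 fold change of -0.26 (camera adjusted p = 9.30e-17; adjusted p = 0.270 with an estimated correlation). The core subunit genes pbs-2, pbs-7 and pbs-5 fell from 221 ± 9.90 to 156 ± 11.9 CPM, from 341 ± 3.81 to 263 ± 12.5 CPM and from 321 ± 7.60 to 247 ± 13.4 CPM. The gene that rose was aip-1 (0.35, adjusted p = 0.0209), an arsenite-inducible gene that is not a core subunit. The aip-1 call was lost without EV replicate 3 (adjusted p = 0.0527) or 4 (0.0529), or mtch-1(RNAi) replicate 2 (0.0554). In the heat shock list, 7 of 14 genes rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0035; adjusted p = 0.289 with an estimated correlation). The small heat shock genes hsp-16.41 and hsp-16.2 rose from 0.625 ± 0.362 to 8.91 ± 5.34 CPM and from 0.575 ± 0.393 to 8.49 ± 5.1 CPM. Reads shared between genes of the hsp-16 family, if any, leave their separate values uncertain. The co-chaperone gene dnj-19 rose from 379 ± 9.43 to 543 ± 47.2 CPM, whereas the heat shock factor gene hsf-1 (-0.24) and sip-1 (-0.45) fell. In mtch-1(RNAi) replicate 1, hsp-16.2 stood at 15.9 CPM, against 4.66 to 7.71 CPM in the other mtch-1(RNAi) samples. Without replicate 1 of both groups, an alternative chosen after seeing the data, 6 heat shock genes rose and 2 fell. In the endoplasmic reticulum stress list, 8 of 17 genes fell and 1 rose, or 9 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.000128; adjusted p = 0.289 with an estimated correlation), with pdi-6 at -0.44 and hsp-3 at -0.35. The gene that rose was the kinase gene pek-1 (0.26, adjusted p = 0.00913). Removing the trend with gene length and level ended this list's call (adjusted p = 0.0665, median -0.12), and with the replicate block 2 genes rose and 9 fell. In the autophagy and lysosome list, 12 of 47 genes fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00775; adjusted p = 0.270 with an estimated correlation). lmp-1 (-0.39) and the vacuolar ATPase genes vha-12 (-0.35) and vha-7 (-0.27) were among them. The stricter count filter (adjusted p = 0.0630) and removal of the trend with gene length and level (adjusted p = 0.20, median -0.06 before and -0.01 after) ended that list call. The number that fell was 6 without EV replicate 4, 7 without mtch-1(RNAi) replicate 4 and 6 without replicate 1 of both groups, and with the replicate block 2 rose and 15 fell.

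Detoxification and defence lists were mixed. Of 57 cytochrome P450 genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (median 0.21, camera adjusted p = 0.0108; adjusted p = 0.289 with an estimated correlation). cyp-14A4 rose by 1.33, cyp-36A1 by 1.02 and cyp-14A1 by 0.86 on the log2 scale, and cyp-34A8 fell (-0.50). Removing the trend with gene length and level ended that list call (adjusted p = 0.167, median 0.08). With the replicate block 21 rose and 4 fell, and without EV replicate 4 the number that rose was 6. Of 53 UDP-glycosyltransferase genes, 11 rose and 3 fell, or 13 and 3 adjusted over the list alone. That list did not pass camera (adjusted p = 0.0589), but did with the replicate block (adjusted p = 0.0462) and without mtch-1(RNAi) replicate 1 (adjusted p = 0.0335). The block gave 14 that rose and 5 that fell. Of 35 glutathione S-transferase genes, 1 rose and 4 fell, or 1 and 3 adjusted over the list alone, with gst-1 at 0.35 and gst-22 at -0.56 (camera adjusted p = 0.787). In the list of SKN-1 targets and glutathione genes, gst-1 rose and gsr-1 (-0.48) and gst-7 (-0.37) fell, which were 3 of 15 genes, with the same counts adjusted over the list alone (camera adjusted p = 0.959). Of 21 antioxidant enzyme genes, 3 rose and 6 fell, or 3 and 7 adjusted over the list alone, with the thioredoxin gene trx-2 at 0.50 and the superoxide dismutase gene sod-2 at -0.35 (camera adjusted p = 0.184). Among 31 innate immunity genes, 5 rose and 5 fell, or 6 and 5 adjusted over the list alone, including lys-4, clec-85 (-0.95) and irg-5 (1.92), and the camera adjusted p was 0.836. Of 13 DAF-16 class I genes, 3 rose and 2 fell, or 4 and 3 adjusted over the list alone, with lea-1 at -0.70 (camera adjusted p = 0.787). Of 6 DAF-16 class II genes, dod-22 rose and dod-19 and dod-17 fell, or 1 and 3 genes adjusted over the list alone (camera adjusted p = 0.184, and 0.0126 with no count filter). The dod-22 call was lost without EV replicate 2 (adjusted p = 0.0643), 3 (0.0576) or 4 (0.0767), or mtch-1(RNAi) replicate 1 (0.0625). The dod-17 call was lost without EV replicate 1 (adjusted p = 0.123), 2 (0.0505) or 3 (0.0688), or mtch-1(RNAi) replicate 1 (0.0616), 3 (0.0749) or 4 (0.105). Of 13 apoptosis genes, 2 rose and 2 fell, with the same counts adjusted over the list alone; cps-6 rose by 0.52 and ced-7 fell by 0.31 on the log2 scale (camera adjusted p = 0.889). With the replicate block, 3 glutathione S-transferase genes rose and 7 fell, 2 genes of the SKN-1 and glutathione list rose and 3 fell, and 11 innate immunity genes rose and 7 fell. The same fit gave 6 that rose and 3 that fell for DAF-16 class I, 1 and 4 for class II, and 1 and 2 for apoptosis.

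Most genes of the eggshell list and many of the oocyte and germline list fell. Of 27 oocyte and germline genes, 14 fell and 2 rose, or 17 and 2 adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 7.03e-06; adjusted p = 0.289 with an estimated correlation). The helicase gene glh-2 fell from 333 ± 11.8 to 245 ± 26.4 CPM and the yolk receptor gene rme-2 from 1373 ± 69.6 to 1084 ± 49.8 CPM, and the meiotic chromosome axis genes him-3 (0.19, adjusted p = 0.00474) and htp-1 (0.15, adjusted p = 0.0239) rose. The htp-1 call was lost without EV replicate 3 (adjusted p = 0.0655), or mtch-1(RNAi) replicate 1 (0.0580) or 2 (0.0774). Of 12 eggshell genes, 9 fell and 0 rose, with the same counts adjusted over the list alone (median -0.28, camera adjusted p = 1.94e-05; adjusted p = 0.270 with an estimated correlation), including cbd-1 from 3183 ± 179.8 to 2489 ± 107.6 CPM and cpg-1 (-0.52). Neither list stayed past the camera threshold once the trend with gene length and level was removed (adjusted p = 0.148 for oocyte and germline, with a median of -0.07, and 0.211 for eggshell, with a median of -0.10). In the list of RNA interference genes, 10 of 17 fell and 0 rose, or 12 and 0 adjusted over the list alone (median -0.23, camera adjusted p = 2.85e-05; adjusted p = 0.270 with an estimated correlation). The RNA-dependent RNA polymerase gene rrf-3 fell by 0.40 and the Argonaute gene sago-2 by 0.82 on the log2 scale, and with the replicate block 1 of these genes rose and 12 fell. Of 13 sperm genes, spe-41 rose (1.13), and this count was the same adjusted over the list alone (camera adjusted p = 0.367), and 2 rose with the replicate block. Of 14 early embryo genes, pha-4 rose (0.59) and tbx-38 (-1.08) and tbx-9 (-0.22) fell, or 1 and 3 genes adjusted over the list alone (camera adjusted p = 0.959). The tbx-38 call was lost without EV replicate 3 (adjusted p = 0.0649) or mtch-1(RNAi) replicate 1 (0.0543). The tbx-9 call was lost with no count filter (adjusted p = 0.0713) and without any single sample except EV replicate 2 (0.0562 to 0.107), and that of pha-4 without replicate 1 of both groups (0.0724), an alternative chosen after seeing the data. None of the 6 vitellogenin genes passed the edgeR test, with vit-2 at 15346 ± 1686 CPM in EV and 15940 ± 1520 CPM in mtch-1(RNAi), and none did so adjusted over the list alone (camera adjusted p = 0.836). vit-5 (0.18, edgeR adjusted p = 0.121) passed as higher in DESeq2 (adjusted p = 0.0285), in limma-voom (0.0428) and with the replicate block (0.0155). The list passed as higher once the trend with gene length and level was removed (adjusted p = 6.40e-07, median 0.33 in place of 0.04). Reads shared between the closely related vitellogenin genes leave their separate values uncertain. Of 25 replication-dependent histone genes, his-61 (-0.77), his-31 (-1.57) and his-40 (-0.89) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.341). Reads shared between histone gene copies leave these values uncertain, and with the replicate block 1 histone gene rose and 4 fell. The his-31 call was lost without EV replicate 4 (adjusted p = 0.0575), and the his-40 call without EV replicate 2 (0.0593) or 4 (0.0640), or mtch-1(RNAi) replicate 1 (0.0515), 2 (0.0516) or 3 (0.0625).

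Among somatic lists, hypodermis genes rose in part. Of 21 hypodermis genes, 6 rose and 0 fell, with the same counts adjusted over the list alone (median 0.19, camera adjusted p = 0.00257; adjusted p = 0.397 with an estimated correlation), including mlt-11 (0.83) and noah-1 (0.81). Of 100 cuticle collagen genes, 14 rose and 1 fell, or 10 and 0 adjusted over the list alone, with dpy-17 at 0.73 and col-83 at 1.83, and the gene that fell was col-149 (-1.53). The col-149 call was lost without EV replicate 1 (adjusted p = 0.0681) or 3 (0.155), without any single mtch-1(RNAi) sample (0.0525 to 0.106), and in limma-voom (0.0577). The collagen list did not pass camera (adjusted p = 0.201), but did without mtch-1(RNAi) replicate 1 (adjusted p = 0.0384) and without mtch-1(RNAi) replicate 2 (adjusted p = 0.00668). The block gave 22 collagen genes that rose and 6 that fell. Of 16 body wall muscle genes, act-4 rose (0.32) and tnt-3 fell (-0.79), with the same counts adjusted over the list alone. With the replicate block 11 of the 16 rose and 1 fell, and without mtch-1(RNAi) replicate 3 the numbers were 7 and 1. That list passed camera (median 0.21, adjusted p = 0.0470; adjusted p = 0.833 with an estimated correlation), but not without EV replicate 3 (adjusted p = 0.218), EV replicate 4 (adjusted p = 0.173), mtch-1(RNAi) replicate 1 (adjusted p = 0.261), mtch-1(RNAi) replicate 2 (adjusted p = 0.0572) or mtch-1(RNAi) replicate 4 (adjusted p = 0.0593). Upper-quartile scaling (adjusted p = 0.0544), the stricter count filter (0.0522) and fry (0.466) also ended that call. The act-4 call was lost without EV replicate 3 (adjusted p = 0.0653) or 4 (0.0681), or mtch-1(RNAi) replicate 1 (0.0614) or 4 (0.0572). Of 80 cytosolic ribosomal protein genes, 7 rose and 2 fell, or 3 and 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.0132; adjusted p = 0.873 with an estimated correlation), with rps-21 at 0.25, rps-6 at -0.30 and rpl-5 at -0.16. The list call was lost without EV replicate 3 (adjusted p = 0.310) or mtch-1(RNAi) replicate 2 (adjusted p = 0.188), and in fry (adjusted p = 0.448). The number that rose was 14 with the replicate block (4 fell) and in limma-voom, 13 in DESeq2, 12 with the stricter count filter or without EV replicate 2, and 3 without mtch-1(RNAi) replicate 2. The rpl-5 call was lost without any single sample except EV replicate 3 (adjusted p = 0.0629 to 0.135), with DESeq2-type (0.0503) or upper-quartile scaling (0.0875), with no (0.0625) or the stricter count filter (0.0754), and without the 50 most abundant genes (0.0600). Of 19 neuronal genes, 0 passed the test, also adjusted over the list alone (camera adjusted p = 0.836), with snb-1 at 235 ± 8.37 CPM in EV and 226 ± 9.80 CPM in mtch-1(RNAi). In the blocked fit, 1 neuronal gene rose. Of 13 pharynx genes, phat-3 fell (-1.22), with the same count adjusted over the list alone (camera adjusted p = 0.787). Of 15 intestine genes, ftn-1 and the metallothionein gene mtl-2 (0.25) rose and cpr-1 (-0.41) fell, or 2 and 3 genes adjusted over the list alone (camera adjusted p = 0.478). With the replicate block, 3 intestine genes rose and 7 fell, and 1 pharynx gene rose and 2 fell. The mtl-2 call was lost without EV replicate 3 (adjusted p = 0.0527) or 4 (0.0598), or mtch-1(RNAi) replicate 2 (0.0571) or 4 (0.0592).

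**Figure D3:**
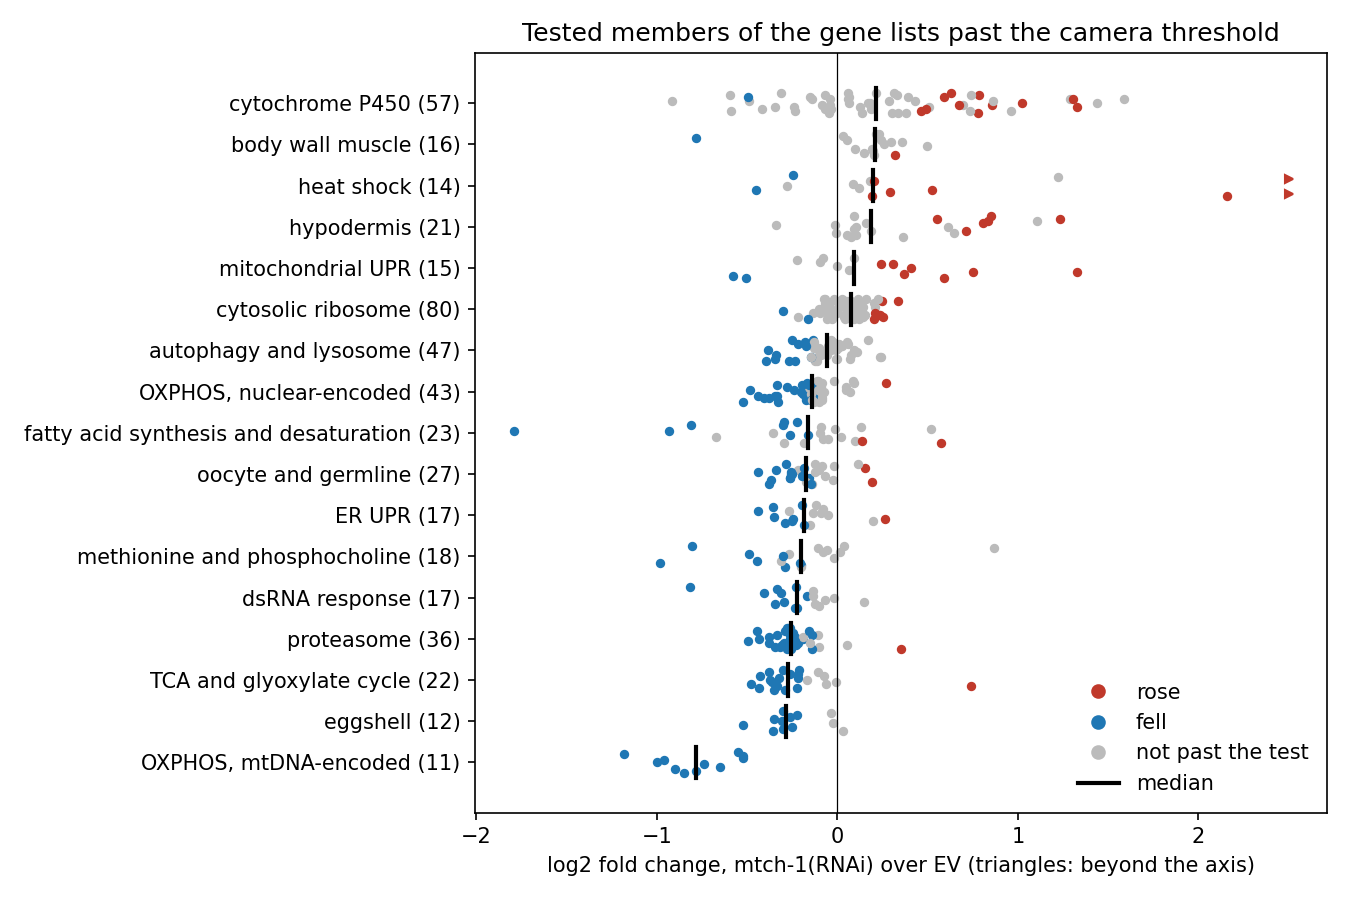
Log2 fold change of mtch-1(RNAi) over EV for each tested member of the 17 lists past the camera threshold with the preset correlation, with the number tested in brackets. Red points rose, blue points fell, grey points did not pass the edgeR test, and bars are medians, from -0.79 for the mitochondrial DNA-encoded list to 0.21 for cytochrome P450.

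In all, 17 of the 40 lists passed camera with the preset correlation and 0 with an estimated one, where 7 had an unadjusted p under 0.05, so the camera calls rest on that setting. fry, which asks only whether a list's genes move one way, called 20, among them iron and heme (adjusted p = 0.0356), DAF-16 class II (0.0282), sperm (0.00213), UDP-glycosyltransferases (0.00926) and histones (0.0374), which camera did not call. Of the 17 lists, fry called all but body wall muscle (adjusted p = 0.466) and cytosolic ribosome (0.448). Another split of the 8 samples, which set EV replicates 1 to 3 and mtch-1(RNAi) replicate 1 against the rest, called 19 lists while changing 0 genes. That split still sets most EV samples against most mtch-1(RNAi) samples, so it keeps part of the real contrast. The median, mean or camera direction differed in sign for the glycolysis, intestine, neuron, iron and heme, early embryo, apoptosis, carrier, fatty acid oxidation, and SKN-1 and glutathione lists, and camera and fry differed in direction for innate immunity.

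The authors' deposited table called 1394 genes higher and 1882 lower at an adjusted p under 0.05, of which 240 and 66 changed by at least 2-fold. Of the 3053 genes changed in the edgeR test, 2974 (97.4%) were also called in the authors' deposited table, and 0 in the opposite direction. The authors' deposited table gives mtch-1 a log2 fold change of -2.57.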

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

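The tests of the mitochondrial and heat shock patterns, both tests of the germline share and the separate trend tests for parts of the lists were chosen after the results were seen. The trend test on all 5 lists was chosen after the list results were seen, but its criterion was set before its own result was seen. The counts over other splits of the samples were set before their results were seen.

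The real grouping gave more changed genes than any other split of the samples. Of the 35 splits of the 8 samples into 4 and 4, only 1, the real one, gave as many as 3053 genes, and the highest other gave 33. For changes of at least 2-fold, again only 1 split gave as many as 307, and the highest other gave 23. Among the 8 splits that part all 4 pairs of same-numbered samples, the highest other gave 0 genes on both counts. Every other split mixes EV and mtch-1(RNAi) samples, so the real difference widens the spread within its sides and holds its count down. These counts therefore do not measure how many of the 3053 calls are false. For the gene lists chance could not be excluded, but the splits cannot decide this, because some of them keep part of the real contrast. As many as 17 lists were called by 2 of the 35 splits, the real one included, and the highest other called 19. Among the 8 splits that part all pairs, the highest other called 15. The split with 19 lists set EV replicates 1 to 3 and mtch-1(RNAi) replicate 1 against the rest, and the median over the other splits was 8.5 lists. Splits like it put 3 samples of 1 group with 1 of the other, which keeps part of the real contrast. They called 10 to 19 lists, against 0 to 9 for splits with 2 samples of each group on each side.

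The opposite moves of mitochondrial mRNAs and rRNAs may reflect changed processing or stability of mitochondrial transcripts, which was not tested. A difference in library size or scaling would leave their ratio within a sample alone, but the ratio differed by 2.06 on the log2 scale, with no overlap between groups. Fewer mitochondrial genomes would not raise the rRNAs, of which the smaller log2 fold change was 1.26 (SE 0.08), but for the fall of the mRNAs this stays open. More rRNA of every kind carried into the mtch-1(RNAi) libraries would raise cytosolic rRNA genes, whose median log2 fold change was -0.11. A change in the carry-over of mitochondrial rRNA alone would not raise them, and stays open. How the libraries were selected for RNA type is not given in the sources used here, so a change in the polyadenylation of mitochondrial rRNA, which can decide how much of it is captured, stays open, and with it whether the rRNA itself rose.

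The oocyte, eggshell, proteasome, citric acid cycle and RNA interference lists were lower together, which may in part reflect a smaller share of germ line and eggs in the animals. Such a loss would raise the markers of every somatic tissue alike. The medians of 5 somatic lists spread over 0.34 on the log2 scale, from intestine (-0.14) to body wall muscle (0.21). The exact permutation test, which ignores the pairs, used sample scores of these 2 lists and not the medians. The changes in score differed by only 0.08 (exact permutation p = 0.800), so that test cannot decide whether the medians differ. By these scores all 5 somatic lists were higher in mtch-1(RNAi), from 0.06 for neurons to 0.37 for hypodermis, with intestine at 0.07. The lowest exact permutation p of the 5 was 0.0571, for hypodermis. Within the 4 same-numbered pairs the muscle median lay above the intestine median in all 4, by 0.36 on average (SE 0.12), and with the replicate block 11 muscle genes rose and 7 intestine genes fell, but these lists were picked as the extremes and the exact sign-flip p of 0.125 is the smallest 4 pairs allow, so this cannot be told apart. After a trend with gene length and expression level was removed, 3 of the 5 lists were still lower by camera with the preset correlation of 0.01. They were the proteasome (adjusted p = 4.11e-11), citric acid cycle (8.53e-06) and RNA interference lists (0.0074). Their medians were then -0.20, -0.19 and -0.20, against -0.26, -0.28 and -0.23 before, which argues against that trend as their whole cause. Their estimated correlations were higher, at 0.35, 0.14 and 0.11. The trend-removed test was not run with these estimates, so its p-values may be too small. Of the 2 germline lists 0 stayed past the threshold. The median shrank from -0.17 (quartiles -0.26 and -0.09) to -0.07 (-0.15 and 0.03) for oocyte and germline (adjusted p = 0.148). For eggshell it shrank from -0.28 (-0.32 and -0.18) to -0.10 (-0.18 and -0.05) (adjusted p = 0.211). The trend could account for these falls, though removing it would also remove a real fall of abundant germline transcripts. The same removal moved the vitellogenin median from 0.04 to 0.33.

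In the heat shock list 7 of 14 genes rose and 2 fell, and hsp-16.2, hsp-16.41 and hsp-70 were highest in mtch-1(RNAi) replicate 1. Handling of mtch-1(RNAi) replicate 1 alone could have raised them, but without that sample 6 heat shock genes still rose, against 7 with all samples. hsp-70 was higher in all 4 same-numbered pairs, by 2.37, 2.05, 1.23 and 1.61 on the log2 scale. Handling that differed between the groups as a whole was not tested and cannot be separated from the RNAi.

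Some samples lay apart from the other 3 of their group in a named gene or sample measure. The gap to the nearest value was large against the range of the 4 values. It could still be small in CPM, as for atfs-1 and tbx-9. Such a gap was found in 17 of 272 groups of 4, and chance alone gives about 1 in 20, or 13.6. In EV samples, pud-3 stood at 43.9 CPM in replicate 2 (others 20.3 to 21.2), irg-4 at 7.28 CPM in replicate 3 (others 2.23 to 2.48) and osg-1 at 4.31 CPM in replicate 1 (others 2.65 to 2.89). Further EV values were timm-23 at 121.6 CPM in replicate 2 (others 111 to 113), atfs-1 at 146 CPM in replicate 3 (others 151 to 152), cyp-14A4 at 1.98 CPM in replicate 1 (others 1.55 to 1.61), vha-12 at 269 CPM in replicate 4 (others 247 to 250.0) and his-61 at 11.2 CPM in replicate 2 (others 8.93 to 9.31). The small mitochondrial rRNA, MTCE.7, stood at 44.6 CPM in EV replicate 3 (others 35.8 to 36.0), and mitochondrial rRNA made up 0.00774% of that sample's counts (others 0.00595% to 0.00621%). In mtch-1(RNAi) samples, irg-4 stood at 32.9 CPM in replicate 3 (others 11.6 to 13.3) and oma-2 at 747 CPM in replicate 4 (others 824 to 833). In mtch-1(RNAi) replicate 1, pdi-6 stood at 126.0 CPM (others 136 to 138), hsp-3 at 384 CPM (others 413 to 418), trx-2 at 62.3 CPM (others 71.8 to 72.5), tbx-9 at 26.4 CPM (others 27.8 to 27.9) and rrf-3 at 91.5 CPM (others 102 to 103).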

How the results depend on the processing

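No named gene or list that passed the test changed direction under any setting. The tests without replicate 1 of both groups, and those with the trend removed for all lists, were chosen after seeing the data. mtch-1 had log2 fold changes from -2.58 to -2.54 under the other scalings, tests, filters and the replicate block, and from -2.68 to -2.44 when single samples were left out. The number of changed genes was 2854 to 4247 under the former and 2230 to 2893 in the latter. The replicate block gave 4247 changed genes (1983 rose, 2264 fell) and 18 lists. Beyond the UDP-glycosyltransferase list, F31C3.7, F31C3.8, haf-2 and vit-5, which the block brought past the threshold, it changed no other call of a named gene or list. Changes of at least 2-fold were 248 to 340 when single samples were left out. With at least 50 counts in 4 samples they were 139 (102 rose, 37 fell), as that filter leaves 10016 genes to test. With an estimated inter-gene correlation 0 lists passed in place of 17. The estimates for the 17 lists all lay above the preset 0.01, from 0.03 for autophagy and lysosome to 0.76 for body wall muscle. They were 0.35 for the proteasome and 0.69 for the mitochondrial DNA-encoded list. A higher correlation widens the error that camera allows for a list. How far this alone accounts for the lost calls was not tested. Without replicate 1 of both groups, 2033 genes changed and 872 rose, with 6 samples in the fit. The share of calls that were higher was 43.4%, and 49.9% with upper-quartile scaling. Removing a trend with gene length and level left 12 lists past the threshold, with 6 calls lost and 1 gained, each given with its list. Of 160 named genes, 18 lost their call when some single sample was left out. Of the 17 called lists, 13 stayed past the threshold in every such refit. At the threshold of 0.01, 1628 of 1633 genes called here were called in the authors' deposited table. In a simulation with 200 changed genes at this depth and number of samples, edgeR recovered 58.2% of changes of 0.5 on the log2 scale. Small changes can therefore be missed. The share may differ in the real data, where 3053 genes were called.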

Other observations

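Some genes that were almost silent in EV were expressed after mtch-1(RNAi). They fall outside the naming rule and, like all tests in this part, were chosen after their values were seen. C07G1.7 (chromosome IV, 8210906 to 8211847) had 8, 9, 2 and 8 counts in the EV samples and 1417, 1467, 1001 and 1517 in the mtch-1(RNAi) samples, or 0.338 ± 0.165 and 60.9 ± 10.9 CPM (SD, n = 4; edgeR adjusted p = 2.55e-09). ZK177.9 (chromosome II, 5517157 to 5517743) went from 0.126 ± 0.0653 to 10.7 ± 2.85 CPM, and C46A5.1 (chromosome IV) from 0.369 ± 0.288 to 6.56 ± 0.980 CPM. C54E10.1 (chromosome V) had 3 counts over the 4 EV samples and 450 over the mtch-1(RNAi) samples. C07G1.7 and its neighbour C07G1.6, which also rose, lie on the minus strand inside the span of svh-1 on the plus strand. svh-1 rose from 0.810 ± 0.147 to 3.70 ± 0.408 CPM (adjusted p = 3.25e-05), and whether reads were counted by strand is not given in the sources used here, so reads of these 3 genes cannot be assigned with certainty. In all, 171 genes with an EV mean under 1 CPM rose, of which 6 reached 5 CPM after mtch-1(RNAi): C07G1.7, ZK177.9, C46A5.1, C54E10.1, hsp-16.2 and hsp-16.41. More genes had at least 1 count in each mtch-1(RNAi) sample (17869 to 18224) than in any EV sample (17241 to 17655).

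Gene classes taken from the first part of the gene symbol, also chosen after seeing the data, gave 10 of 124 classes with at least 10 tested genes past camera, and 0 with an estimated correlation (adjusted p = 0.780 to 0.821 for the 10). The nuclear pore genes (npp) had 15 of 26 members lower and 0 higher (median log2 fold change -0.18, camera adjusted p = 6.09e-06; adjusted p = 0.797 with an estimated correlation). The secretory pathway genes (sec) had 7 of 19 lower and 0 higher (median -0.15, adjusted p = 0.00151; adjusted p = 0.780 with an estimated correlation). The cuticlin-like genes (cutl) had 5 of 21 higher and 0 lower (median 0.52, adjusted p = 0.00509; adjusted p = 0.797 with an estimated correlation). The proteasome regulatory genes (rpn) had 11 of 13 lower and 0 higher (adjusted p = 9.91e-07), the translation initiation factor genes (eif) 10 of 25 lower and 1 higher (0.0217), the vacuolar ATPase genes (vha) 7 of 20 lower and 0 higher (0.0288), acl genes 4 of 12 and acyl-CoA dehydrogenase genes (acdh) 6 of 11 lower and 0 higher (0.0326 each). The F-box genes (fbxb) had 5 of 81 higher and 0 lower (0.0326) and the cytochrome P450 genes (cyp) 11 of 57 higher and 1 lower (0.0434). The rpn, vha, acdh and cyp classes share genes with lists given above.

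Genes beside mtch-1 were lower as well. rpb-4 (7374495 to 7375237) fell by 0.35, F43E2.1 (7375280 to 7377580) by 0.45 and msra-1 (7363220 to 7364040) by 0.57 on the log2 scale, while insc-1, C07D10.5, hsp-4 and haf-2 did not pass the test. haf-2 (0.24) passed it as higher with the replicate block (adjusted p = 0.00192), with no count filter (0.0388) or the stricter one (0.0496), and without EV replicate 1 (0.0417) or mtch-1(RNAi) replicate 3 (0.0444). A hypothesis, formed and tested after the values were seen, is that lowering may reach genes beside the targeted one. Within 10 kb, 3 of 5 tested neighbours fell, which was so for 2.95% of the 271 other fallen genes with 5 tested neighbours. The share was 2.92% within 5 kb (2 of 2 neighbours), 9.27% within 20 kb (3 of 7) and 19.2% within 25 kb (3 of 10). The result depends on the window, so the hypothesis stays open.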
